A study of Arabidopsis thaliana with 18 samples.

How the data were processed

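Leaves of Arabidopsis thaliana Col-0 were profiled by sequencing of polyadenylated RNA on an Illumina instrument. The 18 libraries fall into 6 groups of 3, from seedlings of 9, 12 and 15 days, before culture and 1 day after culture of detached leaves, as the labels state. The text that describes the series speaks of duplicates, while the labels number 3 replicates per group, and all 3 were used. Each library has 1 deposited table with a line per gene.

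Per the submitters' processing notes, the authors trimmed reads with Trimmomatic (version not given), aligned them to the TAIR10 genome with STAR 2.5.3 and quantified genes with RSEM 1.3.0. Per the file headers, the authors deposited an expected count per gene, which RSEM obtains by sharing reads among the genes they fit, and which is not always whole. Per the file headers, the deposited tables also hold TPM and FPKM, computed by the authors from the same reads with the effective length of each gene. The TPM and FPKM values were not used, because the tests need counts. RSEM splits reads between similar copies, so values of near-identical paralogs are uncertain. Strand use is not stated, so AT4G12490 and AT4G12495, which overlap on opposite strands, cannot be told apart with certainty. The annotation version is not given in the sources used here.

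Gene symbols, products and coordinates were taken from the TAIR10.1 reference annotation, with 37390 of 37686 loci matched. As a check, 16593 of 16745 single-transcript coding genes (99.1%) had the same length in the files and the reference to within 0.5 nt. Coordinates are 1-based on TAIR10.1, all named genes are annotated as protein coding except the pseudogene AT5G35777, and RPS6A and other symbols follow that reference or the fixed gene lists.

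Expected counts were rounded and scaled with edgeR's TMM factors. The largest shift that RLE factors would add to a log2 fold change between groups was 0.0225, so no shift is given per comparison. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 20953. Library totals ranged from 29664089 to 51126114 expected counts, and the common biological coefficient of variation was 0.340. A quasi-likelihood model with 1 mean per group was fitted with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3, and 13 contrasts were tested: culture at each age and on average, age before culture, age after culture, and the differences between ages in the culture response. Adjusted p-values are Benjamini-Hochberg values within a contrast with a threshold of 0.05. Comparisons of the 3 ages share groups: the culture contrasts of different ages share no library, while the age contrasts at 1 time share the libraries of their common age, and calls of such contrasts were not compared with each other. CPM values are given as mean ± SD over 3 libraries. Where a group had 0 counts, a bound was taken against a floor of 3 counts over the group. Where it had 1 to 3, the ratio of scaled counts is given with an exact (Clopper-Pearson) 95% interval. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

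Gene lists were fixed before the data were examined, as were the contrasts, the alternatives named in the plan and the rule for naming genes. There were 28 lists with 448 members (447 distinct loci), of which 433 have the same symbol in the reference. The lists are wound and regeneration AP2/ERF factors, root founder and primordium regulators, auxin biosynthesis, auxin transport, auxin response, cytokinin response, jasmonate biosynthesis, jasmonate response, salicylic acid and immunity, ethylene, abscisic acid and dehydration, early stress and touch, flavonoid and anthocyanin, aliphatic glucosinolate, indole glucosinolate, sugar starvation, leaf senescence, photosynthesis, cell cycle, ribosomal proteins and nucleolus, leaf proliferation factors (GRF, GIF1 and ANT), miR156-targeted SPL, CIN-type TCP, stomatal lineage markers, circadian clock, root tissue markers, shoot meristem and boundary markers, and seed storage markers. The 26 lists with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation. They were also tested with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone.

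The text names 36 genes fixed in advance, among them ERF115, WOX11, LBD16, YUC2, CYCB1;1 and DFR. It also names the 5 genes with the largest change in each direction in the average culture response, the age comparisons of 15 against 9 days and the difference of culture responses, if their mean was at least 5 CPM and their groups did not overlap (for the difference, the differences by replicate number, though these numbers did not pair the 15-day samples). From the lists described it names some called members, taken from the 4 with the largest change and from those that moved against the rest. A member of the lists that this rule would name is not reported here.

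The test was tried on simulated counts drawn from the means and library sizes of the real samples, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes had a mean of at least 5 CPM. They were few beside the calls in the real samples, and counts were drawn independently, with no library standing apart. The shares below may therefore not hold in the real samples or for genes at few counts. For culture at 9 days (20670 genes) 25% and 81% of the changed genes were called. For the average culture response (20644 genes) 75% and 97% were called, for age before culture, 15 against 9 days (20652 genes), 20% and 87%, and for the difference of culture responses between 15 and 9 days (20681 genes) 3% and 63%. False genes among the calls were 6.19%, 3.91%, 7.76% and 1.49%.

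Whether replicate numbers pair the samples was checked from the deviations of libraries from their group means. All 3 numbers correlated above 0.1 in 5 of the 15 pairs of groups, which include culture at 9 days, 12 against 9 days after culture and 15 against 12 days before culture, and the count with the replicate number as a block is given beside those results. Replicate 3 correlated above 0.1 in 15 of 15 pairs, and 14 of 18 libraries correlated best with libraries of their own number. The alternatives were RLE factors, DESeq2 1.42.0, no filter on low counts, a mean of at least 5 CPM, the replicate block, only the compared groups in the fit, additive terms for age and culture, and leaving out each replicate or library. Chosen after the data were seen were a batch term for replicate 3 and leaving out replicate 2 before culture at 12 and 15 days.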

Results

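Polyadenylated RNA was sequenced from the first pair of rosette leaves of Arabidopsis thaliana, ecotype Col-0, a standard laboratory line of thale cress. Seedlings were 9, 12 or 15 days old and grew in constant light on a medium containing sucrose. Leaves were collected before culture or after 1 day of culture as detached explants on B5 medium lacking sucrose. Such explants can form roots at the wounded base, and the 3 ages address how that response differs with seedling age. Each of the 6 combinations of age and culture had 3 libraries, 18 in all, so n = 3 per group throughout. The labels do not say that replicates came from separate batches of plants, so p-values measure the spread between these samples. Library totals, as summed expected counts for replicates 1, 2 and 3, were 36279224, 30493240 and 51126114 before culture and 32264546, 32427054 and 38527757 after culture at 9 days. At 12 days they were 29664089, 34540635 and 37974234 before and 33043189, 34326525 and 30193080 after culture. At 15 days they were 30593396, 36834410 and 41217308 before and 33448002, 34435536 and 49025983 after culture. Of 37686 genes, 20953 had enough counts to be tested. RBCS1A, which encodes a Rubisco small subunit, had the most counts in the 9- and 12-day libraries and in cultured 15-day leaves, and RCA, which encodes Rubisco activase, in 15-day leaves before culture. Log2 fold changes are given with standard errors, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

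Levels are given as CPM, counts scaled to library size with edgeR's factors. The first principal component of log2 CPM held 38.7% of the variance and parted cultured from uncultured leaves, and the second held 28.8%. Correlations between replicates across genes, which are not independent replicates, ranged from 0.906 to 0.986, with the lowest value among 15-day leaves before culture. Replicate 2 before culture at 12 days and at 15 days stood apart from the other libraries of their groups (the 2 odd libraries), and the deviations of these 2 libraries correlated with each other (r = 0.637 across genes). The early stress and touch genes, a list that includes TCH3 and ZAT12, had median deviations of 2.65 and 2.47 log2 units in them, and the sugar starvation genes 1.44 and 1.93. The replicate 3 samples carry different tags in their labels and deviated together in each of the 15 pairs of groups, so counts without replicate 3, which leave replicates 1 and 2, are given beside the totals.

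**Figure D1:**
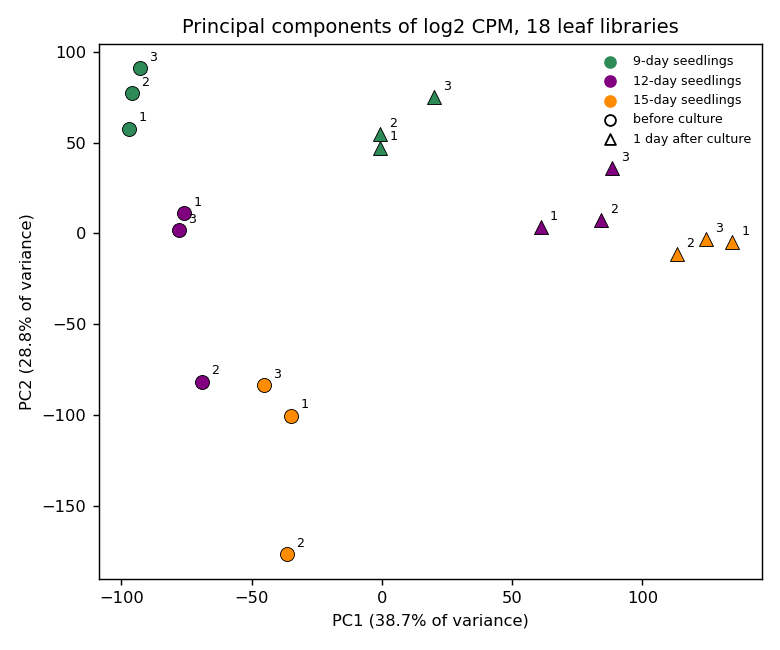
Each point is 1 of the 18 libraries, placed by the first and second principal components of log2 CPM (38.7% and 28.8% of the variance), with color for seedling age, circles for leaves before culture, triangles for leaves 1 day after culture and the replicate number beside each point. Cultured libraries lie to the right of uncultured ones, and replicate 2 before culture at 12 and 15 days lies below the other libraries of its group.

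The first comparison asked how leaves changed over 1 day of culture, averaged over the 3 ages. The class III peroxidase gene PRX52 (AT5G05340, chromosome 5, 1578869 to 1580875, minus strand) rose from 0.0411 ± 0.0123 to 102 ± 19.1 CPM (mean ± SD) at 9 days, and its mean log2 fold change over the ages was 10.40 ± 0.24, adjusted p = 6.58e-13. At each age its cultured and uncultured libraries did not overlap. TH8, which encodes a thioredoxin, rose by 7.58 ± 0.51 at 9 days, and went from 3 to 6895 counts at 12 days, 1937-fold (95% counting interval 662 to 9393), and from 1 to 10262 at 15 days, 7969-fold (95% counting interval 1430 to 314801). The lipid-transfer family genes AT4G12490 (10.08 ± 0.27) and AT4G12500 (10.06 ± 0.28) also rose, though their similar neighbours and the overlapping AT4G12495 make the split of reads among them uncertain. ERF115 (AT5G07310, chromosome 5, 2305551 to 2306837, plus strand), an AP2/ERF factor linked to regeneration after wounding, had 0 counts in the 9 uncultured libraries. After culture it had 122, 121 and 163 summed counts at 9, 12 and 15 days, at least 42.2-, 34.0- and 42.2-fold higher over a floor of 3 counts per group. WOX11 (AT3G03660, chromosome 3, 889166 to 892229, minus strand), a homeobox gene of root founder cells, went from 0 counts to 35, 22 and 19, at least 12.1-, 6.18- and 4.92-fold higher. LBD16 (AT2G42430, chromosome 2, 17663353 to 17665337, plus strand), a lateral organ boundaries factor acting in root initiation, rose by 4.78 ± 0.84 at 12 days and 4.55 ± 0.81 at 15 days. At 9 days it went from 3 to 85 counts, 29.4-fold (95% counting interval 9.72 to 145). Floors and such intervals cover counting error only. The expansin gene EXPA8 fell, at -6.41 ± 0.68, adjusted p = 3.8e-06, as did the shade-response gene PAR1, at -5.41 ± 0.71, and the uncharacterized gene AT3G06070 and AT5G35777, annotated as a pseudogene, at -5.65 ± 0.72 and -5.31 ± 0.60. ADS1, which encodes a fatty acid desaturase, was at -6.25 ± 0.87 at 9 days and reached 0 counts at 15 days, at least 82.4-fold lower.

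Several lists of pigment, defence and hormone genes were called upward. Flavonoid and anthocyanin genes had a median log2 fold change of 4.67 (17 of 19 tested members higher, 17 adjusted over the list alone). Camera gave the flavonoid list adjusted p = 8.34e-22 and adjusted p = 0.0573 with an estimated correlation. The MYB regulator PAP1 rose by 5.32 ± 0.59, adjusted p = 5.03e-06, the bHLH regulator TT8 by 6.24 ± 0.45, and the enzyme genes DFR (AT5G42800, chromosome 5, 17164093 to 17166032, minus strand) and LDOX by 5.48 ± 0.60 and 6.24 ± 0.57. Salicylic acid and immunity genes rose (12 of 17 tested members higher, 12 adjusted over the list alone), with the pathogenesis-related genes PR1 and PR2 at 5.94 ± 0.80 and 4.64 ± 0.59, though at 9 days replicate 3 alone had PR1 well above its uncultured level. The salicylic acid median was 1.70, with camera adjusted p = 2.03e-05 and adjusted p = 0.0997 with an estimated correlation. The wound and regeneration AP2/ERF list was called upward (6 of 13 tested members higher and 1 lower, 6 and 1 adjusted over the list alone). For the wound AP2/ERF list the median was 0.73 (1.46 without the 2 odd libraries, 9 higher and 0 lower), with camera adjusted p = 0.000103 and adjusted p = 0.0573 with an estimated correlation. In it ERF113 rose by 4.84 ± 0.33, while WIND1, a wound-induced dedifferentiation factor, was at -0.14 ± 0.19, adjusted p = 0.573. Abscisic acid and dehydration genes rose (10 of 19 tested members higher, 12 adjusted over the list alone), with the cold- and drought-induced KIN1 at 4.73 ± 0.47 and RD29A at 2.30 ± 0.32. At an abscisic acid median of 0.90, camera gave adjusted p = 0.000246 and adjusted p = 0.323 with an estimated correlation. The leaf senescence list was called upward (7 of 17 tested members higher and 1 lower, 7 and 1 adjusted over the list alone), with SAG13, an oxidoreductase gene, at 7.99 ± 0.53 and the dark-inducible SEN1 as the member that fell, at -4.34 ± 0.87. The leaf senescence median was 0.61, with camera adjusted p = 0.00162 and adjusted p = 0.0997 with an estimated correlation. Jasmonate biosynthesis genes rose (7 of 13 tested members higher, 8 adjusted over the list alone), with the allene oxide cyclase gene AOC1 at 1.37 ± 0.23. For the jasmonate biosynthesis list the median was 0.66 (0.81 without the 2 odd libraries, 11 higher and 0 lower), with camera adjusted p = 0.0121 and adjusted p = 0.323 with an estimated correlation. The jasmonate response list was called upward (8 of 19 tested members higher and 2 lower, 10 and 2 adjusted over the list alone), with VSP2 (AT5G24770, chromosome 5, 8500468 to 8502224, minus strand), a vegetative storage protein gene, at 2.23 ± 0.40. At a jasmonate response median of 0.76 (1.46 without the 2 odd libraries, 14 higher and 0 lower), camera gave adjusted p = 0.00601 and adjusted p = 0.323 with an estimated correlation.

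Growth and photosynthesis genes moved in several directions. Ribosomal protein and nucleolar genes rose (24 of 29 tested members higher, 24 adjusted over the list alone), with the nucleolar gene FIB2 at 1.81 ± 0.29. The ribosomal median was 0.50, with camera adjusted p = 0.000107 and adjusted p = 0.437 with an estimated correlation. The cell cycle list was called upward (22 of 36 tested members higher and 1 lower, 22 and 1 adjusted over the list alone). For the cell cycle list the median was 0.55, with camera adjusted p = 0.00239 and adjusted p = 0.323 with an estimated correlation. The mitotic cyclin CYCB1;1 (AT4G37490, chromosome 4, 17621886 to 17624308, minus strand) rose by 1.24 ± 0.20 and the D-type cyclin CYCD3;2 fell, at -1.43 ± 0.14. Both the ribosomal and the cell cycle lists were called downward at 9 days and upward at 15 days, as given below. Their averages over ages therefore do not describe each age. Photosynthesis genes fell (29 of 37 tested members lower, 34 adjusted over the list alone), with RCA at -1.62 ± 0.14. At a photosynthesis median of -0.73, camera gave adjusted p = 3.04e-09 and adjusted p = 0.323 with an estimated correlation. Cytokinin response genes fell (1 of 10 tested members higher and 9 lower, 1 and 9 adjusted over the list alone). The cytokinin response median was -2.20, with camera adjusted p = 1.61e-05 and adjusted p = 0.0573 with an estimated correlation. Among them the type-A response regulator ARR4 went from 94.7 ± 13.4 to 9.22 ± 1.82 CPM at 9 days and fell on average, at -2.83 ± 0.20, while the cytokinin oxidase gene CKX5 rose by 1.33 ± 0.31, a call lost without replicate 1 or 3. Auxin transport genes fell (1 of 11 tested members higher and 7 lower, 1 and 7 adjusted over the list alone), with the influx carrier gene AUX1 at -1.28 ± 0.15 and the efflux carrier gene PIN4 at -1.48 ± 0.17. For the auxin transport list the median was -0.78, with camera adjusted p = 0.00187 and adjusted p = 0.281 with an estimated correlation. Sugar starvation genes fell (2 of 21 tested members higher and 15 lower, 2 and 15 adjusted over the list alone), with the trehalose-phosphate synthase-like gene TPS9 at -3.64 ± 0.41 against the aminotransferase gene BCAT2 at 2.99 ± 0.49. At a sugar starvation median of -1.20 (-0.64 without the 2 odd libraries, 2 higher and 13 lower), camera gave adjusted p = 0.00249 and adjusted p = 0.437 with an estimated correlation. The growth-regulating factor list was called downward (5 of 10 tested members lower, 7 adjusted over the list alone), with GRF3 at -2.09 ± 0.24, and the median was -0.78 with GRF6 at its bound. The growth factor median was -0.81 (-0.95 without the 2 odd libraries, 0 higher and 9 lower), with camera adjusted p = 0.00601 and adjusted p = 0.323 with an estimated correlation. So was the stomatal lineage list (5 of 10 tested members lower, 5 adjusted over the list alone), with EPFL9, a secreted peptide gene, at -1.80 ± 0.20. For the stomatal list the median was -1.35, with camera adjusted p = 0.00917 and adjusted p = 0.384 with an estimated correlation.

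Auxin synthesis genes moved both ways (6 of 14 tested members higher and 4 lower, 6 and 6 adjusted over the list alone). At an auxin biosynthesis median of -0.01 (0.12 without the 2 odd libraries, 6 higher and 4 lower), camera gave adjusted p = 0.352. The tryptophan synthase subunit gene TSB2 rose by 1.77 ± 0.17, adjusted p = 1.28e-06, the flavin monooxygenase gene YUC2 (AT4G13260, chromosome 4, 7721487 to 7724070, minus strand) fell, at -0.92 ± 0.23, adjusted p = 0.00393, but lost its call without replicate 3, and ASA1, for anthranilate synthase, was at 0.20 ± 0.20, adjusted p = 0.421. YUC8 fell, at -1.92 ± 0.53, and was at -1.06 and no longer called without the 2 odd libraries. LBD29 had 0 counts in all 18 libraries, and WOX12 and YUC4 had at most 5 and 8 counts in any library, too few to test. Auxin response genes were mixed (5 of 15 tested members higher and 5 lower, 5 and 5 adjusted over the list alone), with the conjugating enzyme gene GH3.3 at 4.14 ± 0.65 and the repressor gene IAA29 at -2.15 ± 0.41. The auxin response median was -0.24 (0.12 without the 2 odd libraries, 5 higher and 3 lower), with camera adjusted p = 0.946. The other lists were not called either, and these were root founder and primordium regulators (4 of 8 tested members higher and 3 lower, 4 and 3 adjusted over the list alone) and ethylene genes (2 of 17 tested members higher and 7 lower, 2 and 7 adjusted over the list alone). For root founder genes the median was 0.53, with camera adjusted p = 0.265. Ethylene genes had median -0.53 (-0.33 without the 2 odd libraries, 4 higher and 7 lower), with camera adjusted p = 0.265. SPL genes targeted by miR156 (1 of 11 tested members higher and 3 lower, 1 and 3 adjusted over the list alone), CIN-type TCP genes (1 of 8 tested members lower, 1 adjusted over the list alone) and early stress and touch genes (1 of 13 tested members lower, 0 adjusted over the list alone) were further such lists. The median of SPL genes was -0.40 (-0.33 without the 2 odd libraries, 2 higher and 5 lower), with camera adjusted p = 0.285. For CIN-type TCP genes the median was -0.21 (-0.32 without the 2 odd libraries, 1 higher and 4 lower), with camera adjusted p = 0.410. Stress and touch genes had median -0.55 (-0.12 without the 2 odd libraries, 1 higher and 0 lower), with camera adjusted p = 0.410. The same was so for aliphatic glucosinolate genes (2 of 13 tested members higher, 1 adjusted over the list alone), indole glucosinolate genes (2 of 7 tested members higher and 1 lower, 2 and 1 adjusted over the list alone), circadian clock genes (2 of 11 tested members higher and 3 lower, 2 and 3 adjusted over the list alone) and root tissue markers (2 of 3 tested members higher and 1 lower, 2 and 1 adjusted over the list alone). The median of aliphatic glucosinolate genes was 0.29 (0.02 without the 2 odd libraries, 2 higher and 2 lower), with camera adjusted p = 0.221. For indole glucosinolate genes the median was 0.21 (0.14 without the 2 odd libraries, 1 higher and 1 lower), with camera adjusted p = 0.766. Clock genes had median -0.37 (-0.54 without the 2 odd libraries, 0 higher and 3 lower), with camera adjusted p = 0.352. The median of root tissue genes was 0.86, with camera adjusted p = 0.162.

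Further genes fixed in advance were followed whatever their change. The auxin synthesis gene YUC9 fell, at -1.81 ± 0.69, a call lost without replicate 1 or 3, with the replicate number as a block and with a batch term. LOX2, a lipoxygenase gene, rose by 1.19 ± 0.38, a call lost without replicate 1 or 3. The repressor gene IAA19 fell, at -1.09 ± 0.37, and was at -0.35 and not called without the 2 odd libraries. ARR5, a type-A response regulator, fell, at -1.71 ± 0.43, a call lost without replicate 2. Genes not called were ERF109 (0.28 ± 0.85, adjusted p = 0.815), YUC5 (-2.30 ± 0.93, adjusted p = 0.0552), the jasmonate repressor JAZ10 (0.76 ± 0.51, adjusted p = 0.243), SPL9 (-0.46 ± 0.34, adjusted p = 0.289) and the clock gene CCA1 (-0.81 ± 0.40, adjusted p = 0.108). Without the 2 odd libraries JAZ10 was called higher and SPL9 lower.

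**Figure D2:**
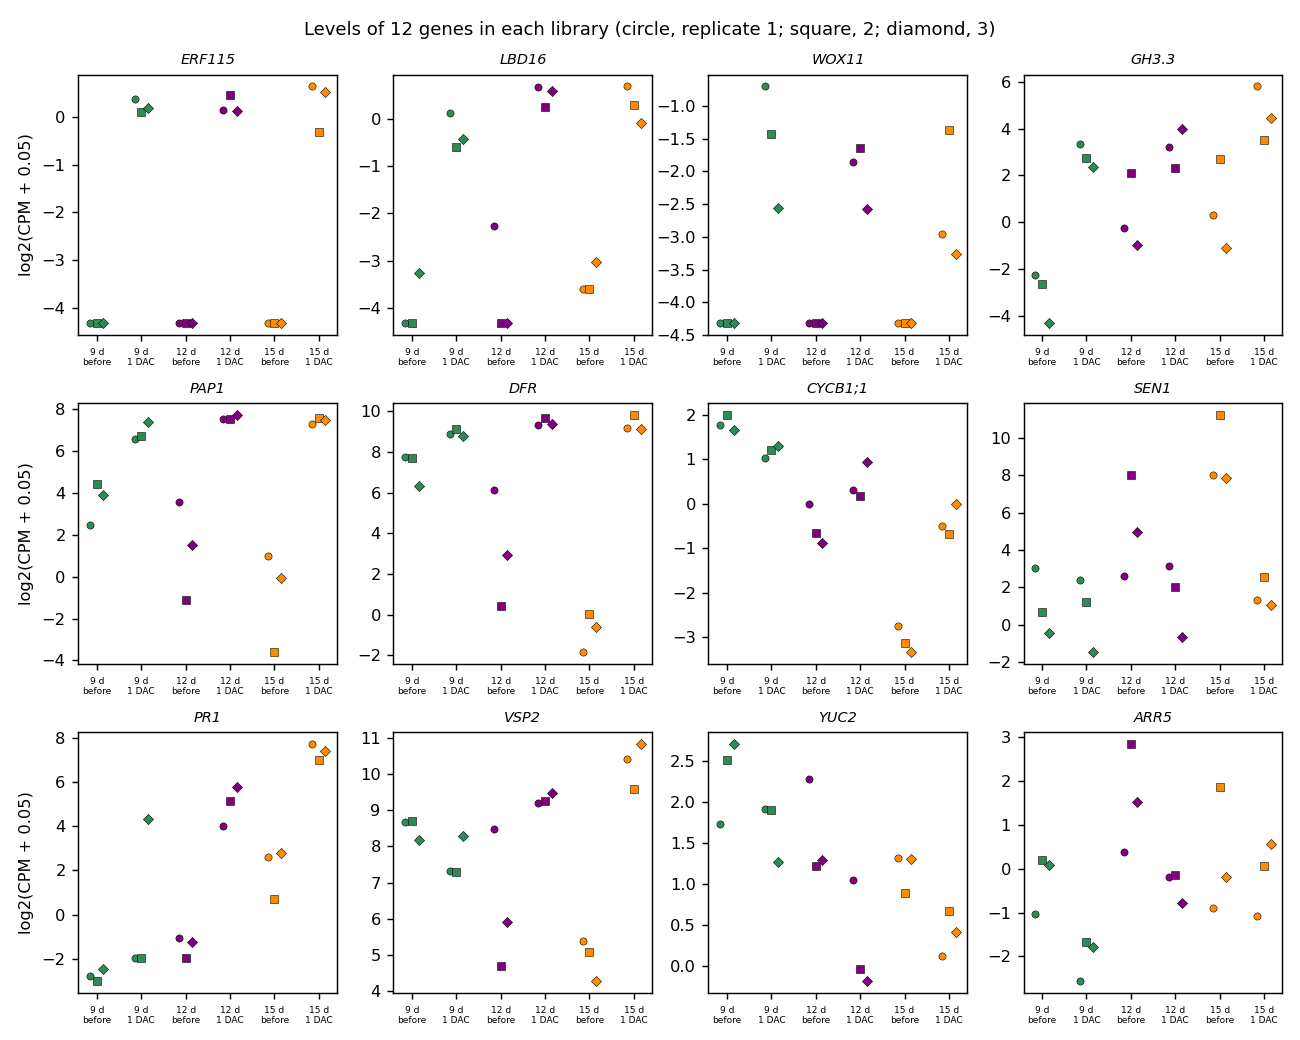
Levels of 12 genes as log2(CPM + 0.05) in each library, with color for seedling age, groups in order of age, before culture and 1 day after culture (1 DAC), and circles, squares and diamonds for replicates 1, 2 and 3. ERF115 and WOX11 sit at the bottom of the axis in the uncultured libraries (0 counts), and SEN1 before culture at 15 days is highest in replicate 2 (2392 CPM).

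In all, 9342 genes changed in the average over ages, 4706 higher and 4636 lower, and 3431 changed at least 2-fold, by edgeR's quasi-likelihood test. Cultured and uncultured libraries did not overlap at any of the 3 ages for 2294 of the 20953 tested genes. The count of called genes was 10113 without the 2 odd libraries, and 5539, 7490 and 7553 without replicates 1, 2 and 3. Culture also meant detachment, 1 more day of age and loss of sucrose, which cannot be separated here.

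Comparisons within each age asked how the response to culture looked in younger and older leaves. The flavonoid and anthocyanin list was called upward at 9 days (8 of 19 tested members higher, 11 adjusted over the list alone), at 12 days (17 of 19 tested members higher, 17 adjusted over the list alone) and at 15 days (17 of 19 tested members higher, 18 adjusted over the list alone). For flavonoid genes the median was 1.79 at 9 days (1.79 without the 2 odd libraries, 14 higher and 0 lower), with camera adjusted p = 2.12e-08 and adjusted p = 0.280 with an estimated correlation. Flavonoid genes had median 4.51 at 12 days, with camera adjusted p = 1.25e-17 and adjusted p = 0.0548 with an estimated correlation. The median of flavonoid genes was 6.73 at 15 days, with camera adjusted p = 7.86e-18 and adjusted p = 0.112 with an estimated correlation. DFR was at 1.54 ± 0.87, adjusted p = 0.312 at 9 days and rose by 10.14 ± 1.28, adjusted p = 3.96e-05 at 15 days, from 0.601 ± 0.367 to 682 ± 185 CPM. PAP1 rose by 3.15 ± 0.91, 5.27 ± 1.01 and 7.52 ± 1.13 at the 3 ages, with the call at 9 days lost without replicate 1 or 3 and that at 12 days without replicate 3. The cell cycle list was called downward at 9 days (8 of 36 tested members lower, 12 adjusted over the list alone) and upward at 15 days (33 of 36 tested members higher and 1 lower, 33 and 1 adjusted over the list alone). For cell cycle genes the median was -0.77 at 9 days (-0.77 without the 2 odd libraries, 0 higher and 15 lower), with camera adjusted p = 1.85e-10 and adjusted p = 0.0512 with an estimated correlation. Cell cycle genes had median 1.98 at 15 days, with camera adjusted p = 4.22e-14 and adjusted p = 0.0793 with an estimated correlation. CYCB1;1 was at -0.64 ± 0.30, adjusted p = 0.211 at 9 days and rose by 3.33 ± 0.40, adjusted p = 2.67e-05 at 15 days. Ribosomal genes were called downward at 9 days (1 of 29 tested members lower, 0 adjusted over the list alone) and upward at 15 days (29 of 29 tested members higher, 29 adjusted over the list alone). The median of ribosomal genes was -0.38 at 9 days (-0.38 without the 2 odd libraries, 0 higher and 6 lower), with camera adjusted p = 0.00120 and adjusted p = 0.533 with an estimated correlation. For ribosomal genes the median was 1.56 at 15 days, with camera adjusted p = 4.81e-16 and adjusted p = 0.226 with an estimated correlation. The cytokinin response list was called downward at 9 days (5 of 10 tested members lower, 8 adjusted over the list alone) and at 12 days (8 of 10 tested members lower, 8 adjusted over the list alone). Cytokinin response genes had median -2.26 at 9 days (-2.26 without the 2 odd libraries, 0 higher and 9 lower), with camera adjusted p = 5.4e-09 and adjusted p = 0.0142 with an estimated correlation. The median of cytokinin response genes was -3.08 at 12 days, with camera adjusted p = 4.54e-09 and adjusted p = 0.0287 with an estimated correlation. Sugar starvation genes fell at 15 days (1 of 21 tested members higher and 17 lower, 1 and 17 adjusted over the list alone). For the sugar starvation list the median was -2.30 (-1.06 without the 2 odd libraries, 2 higher and 13 lower), with camera adjusted p = 0.000256 and adjusted p = 0.379 with an estimated correlation. For the wound AP2/ERF factors at 9 days the median was -0.04, while the mean was 2.08 and the test pointed up (4 of 13 tested members higher, 4 adjusted over the list alone), with ERF113 at 4.31 ± 0.57 and ERF114 at 7.06 ± 0.59. Camera gave the wound AP2/ERF list adjusted p = 0.000568 and adjusted p = 0.0701 with an estimated correlation. Among root tissue markers PYK10, a beta-glucosidase gene, was at -0.74 ± 0.41, adjusted p = 0.298 at 9 days and rose by 3.69 ± 0.45 at 15 days, from 4.93 ± 2.58 to 63.4 ± 5.70 CPM. The nitrate transporter gene NRT2.1 went from 1 to 574 counts at 9 days, 595-fold (95% counting interval 106 to 23543). VSP2 was at -0.81 ± 0.66, adjusted p = 0.520 at 9 days and rose by 5.39 ± 0.80, adjusted p = 0.000128 at 15 days.

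At 9 days 1999 genes (9.54% of those tested) changed by edgeR's quasi-likelihood test, 1219 higher and 780 lower. The count was 3084 with the replicate number as a block, 3844 without the 2 odd libraries, and 316, 1003 and 840 without replicates 1, 2 and 3. At 12 days 4136 genes (19.7%) changed, 2182 higher and 1954 lower (1668, 2578 and 2089 without replicates 1, 2 and 3). At 15 days 8778 (41.9%) changed, 4417 higher and 4361 lower (4495, 6612 and 6707 without replicates 1, 2 and 3). At all 3 ages 651 genes rose, where independent sets of these sizes would share 26.8, and 315 fell, where they would share 15.1. These 966 shared genes became 1625 without the 2 odd libraries and 193, 592 and 370 without replicates 1, 2 and 3. Between 9 and 15 days 160 genes were called in opposite directions.

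**Figure D3:**
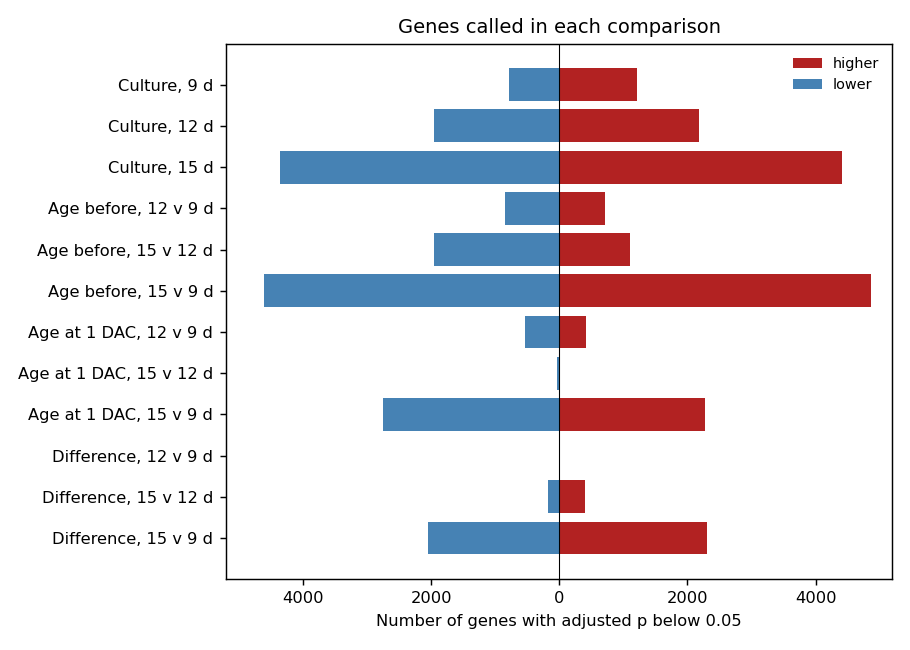
Bars give the number of genes with adjusted p below 0.05 in each comparison, higher to the right and lower to the left, for culture at each age, for age before culture and at 1 day after culture (1 DAC), and for the difference in culture response between ages. Genes called for culture number 1999 at 9 days and 8778 at 15 days.

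Ages were compared before culture to describe the starting state of the leaves, here as 15 against 9 days. Cell cycle genes were lower at 15 days (36 of 36 tested members lower, 36 adjusted over the list alone). At a cell cycle median of -3.34, camera gave adjusted p = 6.3e-40 and adjusted p = 0.00127 with an estimated correlation. The cytokinesis kinesin gene HIK went from 9.31 ± 0.786 to 0.214 ± 0.0191 CPM, a change of -5.42 ± 0.37, adjusted p = 1.13e-07, and CYCB1;1 was at -5.58 ± 0.40. Stomatal lineage markers were lower (9 of 10 tested members lower, 9 adjusted over the list alone). The stomatal median was -6.14, with camera adjusted p = 5.06e-09 and adjusted p = 0.103 with an estimated correlation. The stomatal protease gene SDD1 was at -8.27 ± 1.05, and MUTE, a bHLH gene of guard cell precursors, went from 418 to 2 counts, 188-fold (95% counting interval 51.8 to 1560). Flavonoid and anthocyanin genes were lower (1 of 19 tested members higher and 17 lower, 1 and 17 adjusted over the list alone), with DFR at -8.11 ± 1.19 against the repressor gene MYBL2 at 3.22 ± 0.67. For the flavonoid list the median was -3.98, with camera adjusted p = 7.53e-09 and adjusted p = 0.324 with an estimated correlation. Ribosomal genes were lower (22 of 29 tested members lower, 23 adjusted over the list alone), with RPS6A at -2.27 ± 0.27. At a ribosomal median of -0.98, camera gave adjusted p = 6.74e-07 and adjusted p = 0.431 with an estimated correlation. The growth-regulating factor list was called downward (5 of 10 tested members lower, 5 adjusted over the list alone), with the AP2 growth gene ANT at -2.85 ± 0.29 and GRF4 at -3.91 ± 0.46. The growth factor median was -0.96, with camera adjusted p = 0.0447 and adjusted p = 0.431 with an estimated correlation. The auxin carrier gene LAX2 fell, at -2.27 ± 0.19. YUC2 was at 5.13 ± 1.66 CPM at 9 days and 2.22 ± 0.360 CPM at 15 days, a change of -1.21 ± 0.39, adjusted p = 0.0203, and lost its call without replicate 2 or 3.

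Senescence and starvation genes were higher at 15 than at 9 days. In the leaf senescence list (12 of 17 tested members higher, 13 adjusted over the list alone), the NAC gene ORE1 (AT5G39610, chromosome 5, 15858398 to 15859911, minus strand) went from 0.228 ± 0.177 to 64.0 ± 19.1 CPM, by 7.97 ± 0.98, adjusted p = 1.94e-05, and SAG12 had 0 counts in all 18 libraries. For the leaf senescence list the median was 1.66, with camera adjusted p = 6.32e-05 and adjusted p = 0.0244 with an estimated correlation. SEN1 (AT4G35770, chromosome 4, 16944878 to 16946266, plus strand) rose by 8.12 ± 1.78, adjusted p = 0.00205, with 256, 2392 and 235 CPM in the 3 libraries at 15 days. Sugar starvation genes were higher (16 of 21 tested members higher, 17 adjusted over the list alone). At a sugar starvation median of 2.29 (1.31 without the 2 odd libraries, 11 higher and 1 lower), camera gave adjusted p = 0.00122 and adjusted p = 0.431 with an estimated correlation. ASN1, which encodes asparagine synthetase, was at 5.79 ± 2.06 with all libraries and at 1.03, not called, without the 2 odd ones, and the AP2/ERF gene ABR1 turned from 7.55 ± 2.32 to -1.17. Abscisic acid genes (8 of 19 tested members higher, 8 adjusted over the list alone), ethylene genes (8 of 17 tested members higher, 8 adjusted over the list alone) and clock genes (5 of 11 tested members higher, 5 adjusted over the list alone) were also called upward. The median of abscisic acid genes was 1.24 (1.46 without the 2 odd libraries, 13 higher and 0 lower), with camera adjusted p = 0.0108 and adjusted p = 0.431 with an estimated correlation. For ethylene genes the median was 0.87 (0.54 without the 2 odd libraries, 7 higher and 1 lower), with camera adjusted p = 0.0223 and adjusted p = 0.431 with an estimated correlation. Clock genes had median 1.18 (1.23 without the 2 odd libraries, 3 higher and 0 lower), with camera adjusted p = 0.0488 and adjusted p = 0.193 with an estimated correlation. The galactinol synthase gene GolS2 rose by 9.91 ± 1.36 and the methylthioalkylmalate synthase gene MAM3 by 6.18 ± 0.55. Among markers of other tissues, PYK10 went from 50.4 ± 6.97 to 4.93 ± 2.58 CPM, a change of -3.36 ± 0.45. CRA1, the tested member of the seed storage list, went from 34 to 3 counts, 10.2-fold (95% counting interval 3.21 to 52.0). KNAT6, that of the shoot meristem and boundary list, was lower at 15 days before culture and at -1.38 ± 0.38 after it, both calls lost without any 1 replicate.

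Of 9 other genes with large differences between 15 and 9 days before culture, 6 had at most 3 counts at 1 age. Higher at 15 days were DIN11, an oxygenase gene (3 to 2302 counts, 852-fold (95% counting interval 291 to 4133)), the amino acid transporter gene LHT7 (2 to 1463 counts, 812-fold (95% counting interval 224 to 6710)) and the glycosyl hydrolase gene AT4G16260 (2 to 1162 counts, 645-fold (95% counting interval 178 to 5331)). The berberine-family gene AT1G26380 rose by 8.69 ± 2.12. Lower were the bHLH genes bHLH38 (5760 to 1 counts, 5190-fold (95% counting interval 931 to 205028)) and bHLH39 (4028 to 1 counts, 3629-fold (95% counting interval 651 to 143388)) and AT5G62210 (3733 to 3 counts, 1121-fold (95% counting interval 383 to 5439)). AT5G45670, a lipase family gene, and AT2G33850 fell, at -9.83 ± 0.72 and -9.71 ± 0.72.

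Between 15 and 9 days before culture 9471 genes differed, 4858 higher and 4613 lower. The groups did not overlap for 10095 of the 20953 tested genes (48.2%), where 10% of unchanged genes would not. The count of called genes was 8970 without the 2 odd libraries, and 5920, 6498 and 7558 without replicates 1, 2 and 3. From 9 to 12 days 1559 genes differed, 717 higher and 842 lower (146, 244 and 1055 without replicates 1, 2 and 3), and cell cycle genes were lower (22 of 36 tested members lower, 26 adjusted over the list alone). The cell cycle median was -1.38, with camera adjusted p = 5.62e-34 and adjusted p = 0.00162 with an estimated correlation. From 12 to 15 days 3048 differed, 1098 higher and 1950 lower (4665 with the replicate number as a block, and 551, 2090 and 1159 without replicates 1, 2 and 3). With only the compared groups in the fit far fewer differed, as given in the section on processing. Cell cycle genes were lower again from 12 to 15 days (31 of 36 tested members lower, 33 adjusted over the list alone). For the cell cycle list the median was -1.86, with camera adjusted p = 8.81e-34 and adjusted p = 0.00237 with an estimated correlation. HIK was at 2.27 ± 0.469 CPM at 12 days.

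The same ages were compared after 1 day of culture, to ask which differences remained in the explants. Stomatal lineage markers were lower in 15-day than in 9-day explants (10 of 10 tested members lower, 10 adjusted over the list alone), with SDD1 at -5.94 ± 0.89, adjusted p = 0.000396 and the bHLH gene SPCH going from 317 to 3 counts, 127-fold (95% counting interval 43.1 to 619.6). At a stomatal median of -5.22, camera gave adjusted p = 3.61e-15 and adjusted p = 0.0258 with an estimated correlation. Cell cycle genes were lower (0 of 36 tested members higher and 20 lower, 1 and 23 adjusted over the list alone), with CDC20.1, an activator of the anaphase-promoting complex, at -2.10 ± 0.18 and the cyclin CYCB1;2 at -1.97 ± 0.24. The cell cycle median was -1.10 (-1.11 without the 2 odd libraries, 1 higher and 23 lower), with camera adjusted p = 8.67e-07 and adjusted p = 0.0978 with an estimated correlation. Ribosomal genes were higher (24 of 29 tested members higher, 28 adjusted over the list alone), with RPL3A at 1.04 ± 0.18. For the ribosomal list the median was 0.86, with camera adjusted p = 3.16e-10 and adjusted p = 0.247 with an estimated correlation. Salicylic acid genes were higher (14 of 17 tested members higher, 15 adjusted over the list alone), with the transcription factor gene WRKY38 at 4.93 ± 0.71 and PR2 at 5.23 ± 1.05. At a salicylic acid median of 2.60, camera gave adjusted p = 2.15e-10 and adjusted p = 0.0258 with an estimated correlation. Senescence genes were higher (9 of 17 tested members higher, 11 adjusted over the list alone), with SAG13 at 4.37 ± 0.74. The leaf senescence median was 1.84, with camera adjusted p = 4.02e-05 and adjusted p = 0.0258 with an estimated correlation. Abscisic acid genes were higher (11 of 19 tested members higher, 13 adjusted over the list alone), with the dehydration gene RD29B at 7.15 ± 1.29. For the abscisic acid list the median was 1.60, with camera adjusted p = 1.25e-06 and adjusted p = 0.0978 with an estimated correlation. The jasmonate response list was called upward (9 of 19 tested members higher, 11 adjusted over the list alone), with VSP1 at 4.23 ± 0.92. At a jasmonate response median of 1.83, camera gave adjusted p = 4.08e-05 and adjusted p = 0.103 with an estimated correlation. The lipid transfer protein genes LTP3 and LTP4 rose by 7.85 ± 1.34 and 9.28 ± 1.87, DXPS1, a deoxyxylulose phosphate synthase gene, by 10.58 ± 1.55 and LEA7 by 9.05 ± 1.66, the last a call lost without replicate 3. AT3G17520, of the same family as LEA7, went from 3 to 1797 counts, 498-fold (95% counting interval 170.1 to 2417), and also lost its call without replicate 3. The germin gene GER3, AT2G33850 and the glycine-rich protein gene AT4G29020 fell, at -8.81 ± 0.82, -8.67 ± 0.69 and -7.57 ± 0.55. AT1G06360, a desaturase family gene, fell from 9.17 ± 1.54 to 0.0323 ± 0.0182 CPM. AT3G46490 went from 1243 to 2 counts, 748-fold (95% counting interval 206 to 6179). RPL3A, PR2 and VSP1 lost their calls without replicate 1.

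Photosynthesis genes were lower in 15-day explants (22 of 37 tested members lower, 30 adjusted over the list alone), with the Rubisco gene RBCS3B at -1.97 ± 0.28. The photosynthesis median was -1.05, with camera adjusted p = 1.01e-10 and adjusted p = 0.284 with an estimated correlation. Auxin transport genes were lower (6 of 11 tested members lower, 7 adjusted over the list alone), with LAX2 at -2.19 ± 0.19 and PIN4 at -2.11 ± 0.30. For the auxin transport list the median was -1.09, with camera adjusted p = 7.41e-06 and adjusted p = 0.0978 with an estimated correlation. Growth-regulating factors were lower (6 of 10 tested members lower, 8 adjusted over the list alone), with GRF3 at -2.60 ± 0.43. At a growth factor median of -1.69, camera gave adjusted p = 4.02e-05 and adjusted p = 0.0978 with an estimated correlation. YUC2 was lower, at -1.34 ± 0.40, adjusted p = 0.0234, while ASA1 (1.33 ± 0.34, adjusted p = 0.0119) and the tryptophan synthase gene TSA1 (1.13 ± 0.22) were higher. YUC2 lost its call without any 1 replicate, ASA1 without replicate 1 or 3 and TSA1 without replicate 1. Aliphatic glucosinolate genes (3 of 13 tested members higher, 5 adjusted over the list alone) and indole glucosinolate genes (3 of 7 tested members higher, 6 adjusted over the list alone) were called upward. The median of aliphatic glucosinolate genes was 1.38 (1.37 without the 2 odd libraries, 8 higher and 0 lower), with camera adjusted p = 0.00279 and adjusted p = 0.481 with an estimated correlation. For indole glucosinolate genes the median was 1.13 (1.11 without the 2 odd libraries, 5 higher and 0 lower), with camera adjusted p = 0.0141 and adjusted p = 0.103 with an estimated correlation. MAM3 went from 4.04 ± 1.29 to 49.1 ± 7.29 CPM between 9- and 15-day explants. The SPL list was not called (4 of 11 tested members lower, 5 adjusted over the list alone). At an SPL median of -0.54 (-0.55 without the 2 odd libraries, 1 higher and 6 lower), camera gave adjusted p = 0.0536. LBD16 was at 0.62 ± 0.61, adjusted p = 0.509, and GH3.3 at 2.05 ± 0.94, adjusted p = 0.129.

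In total 5022 genes differed between 15 and 9 days after culture, 2272 higher and 2750 lower (883, 3382 and 3112 without replicates 1, 2 and 3), by edgeR's quasi-likelihood test. The groups did not overlap for 10593 of the 20953 tested genes (50.6%), where 10% of unchanged genes would not. Of the 9471 genes that differed by age before culture, 2601 differed the same way after it, 954 higher where 527 would overlap by chance and 1647 lower where 605 would, and 427 differed the opposite way. Explants of 12 and 9 days differed in 942 genes (1626 with the replicate number as a block, 2023 without the 2 odd libraries, and 50, 96 and 148 without replicates 1, 2 and 3). Those of 15 and 12 days differed in 41 by edgeR, with 2783 at an unadjusted p under 0.05, against 723 without the 2 odd libraries and 759 by DESeq2. The edgeR counts were 0, 5 and 0 without replicates 1, 2 and 3, with 830, 2520 and 2562 at an unadjusted p under 0.05.

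The last comparison asked whether the change over culture itself differed between 15 and 9 days, as the log2 change at 15 days minus that at 9 days. Cell cycle genes differed upward (32 of 36 tested members with an upward difference, 34 adjusted over the list alone), with CYCB1;1 at 3.97 ± 0.50, adjusted p = 0.000273 and the replication clamp gene PCNA1 at 3.89 ± 0.54. The cell cycle median was 2.78, with camera adjusted p = 1.05e-32 and adjusted p = 0.00228 with an estimated correlation. Ribosomal genes (27 of 29 tested members with an upward difference, 29 adjusted over the list alone) and flavonoid and anthocyanin genes (14 of 19 tested members with an upward difference, 16 adjusted over the list alone) did too, with RPS6A at 3.37 ± 0.37 and LDOX at 8.60 ± 1.28. For ribosomal genes the median was 1.93, with camera adjusted p = 1.64e-25 and adjusted p = 0.116 with an estimated correlation. Flavonoid genes had median 4.40, with camera adjusted p = 4.33e-15 and adjusted p = 0.116 with an estimated correlation. Salicylic acid genes had a median difference of 1.23, or 1.32 with ALD1 at its bound (4 of 17 tested members with an upward difference, 6 adjusted over the list alone). Camera gave the salicylic acid list adjusted p = 0.00840 and adjusted p = 0.329 with an estimated correlation (median 1.44 without the 2 odd libraries, 7 upward and 0 downward). The vegetative storage gene VSP2 had a difference of 6.20 ± 1.01 and was at 31.5 ± 11.2 CPM before and 1323 ± 527 CPM after culture at 15 days. Called downward were the lists of sugar starvation (9 of 21 tested members with a downward difference, 11 adjusted over the list alone), ethylene (7 of 17 tested members with a downward difference, 8 adjusted over the list alone), auxin response (4 of 15 tested members with a downward difference, 5 adjusted over the list alone), photosynthesis (5 of 37 tested members with a downward difference, 3 adjusted over the list alone) and circadian clock genes (2 of 11 tested members with a downward difference, 2 adjusted over the list alone). The median of sugar starvation genes was -2.21 (-1.14 without the 2 odd libraries, 1 upward and 9 downward), with camera adjusted p = 0.000564 and adjusted p = 0.497 with an estimated correlation. For ethylene genes the median was -1.23 (-0.81 without the 2 odd libraries, 0 upward and 7 downward), with camera adjusted p = 0.00282 and adjusted p = 0.427 with an estimated correlation. Auxin response genes had median -1.85 (-0.85 without the 2 odd libraries, 0 upward and 4 downward), with camera adjusted p = 0.00723 and adjusted p = 0.403 with an estimated correlation. The median of photosynthesis genes was -0.77, with camera adjusted p = 0.000613 and adjusted p = 0.626 with an estimated correlation. For clock genes the median was -1.15 (-1.29 without the 2 odd libraries, 0 upward and 1 downward), with camera adjusted p = 0.0200 and adjusted p = 0.116 with an estimated correlation. IAA29 was at -5.78 ± 1.02 and the defensin gene PDF1.2 at -7.44 ± 1.13.

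By this test 4360 genes differed between 15 and 9 days, 2312 upward and 2048 downward (5109 without the 2 odd libraries, and 762, 1870 and 2278 without replicates 1, 2 and 3). Of the 4360, 1853 rose at 15 days without a call at 9 days, 1528 fell at 15 days without a call at 9 days, 101 fell at 9 and rose at 15 days, and 59 did the reverse. Between 12 and 9 days 11 genes differed by edgeR (50 with the replicate number as a block, 58 without the 2 odd libraries, 433 by DESeq2, and 2217 at an unadjusted p under 0.05). Without replicates 1, 2 or 3 edgeR called 0 of them, with 1541, 1177 and 2119 at an unadjusted p under 0.05. Between 15 and 12 days 582 differed, 410 upward and 172 downward (1506 without the 2 odd libraries, 1473 by DESeq2, and 3731 at an unadjusted p under 0.05). The edgeR counts were 0, 88 and 0 without replicates 1, 2 and 3, with 1906, 3265 and 2881 at an unadjusted p under 0.05.

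**Figure D4:**
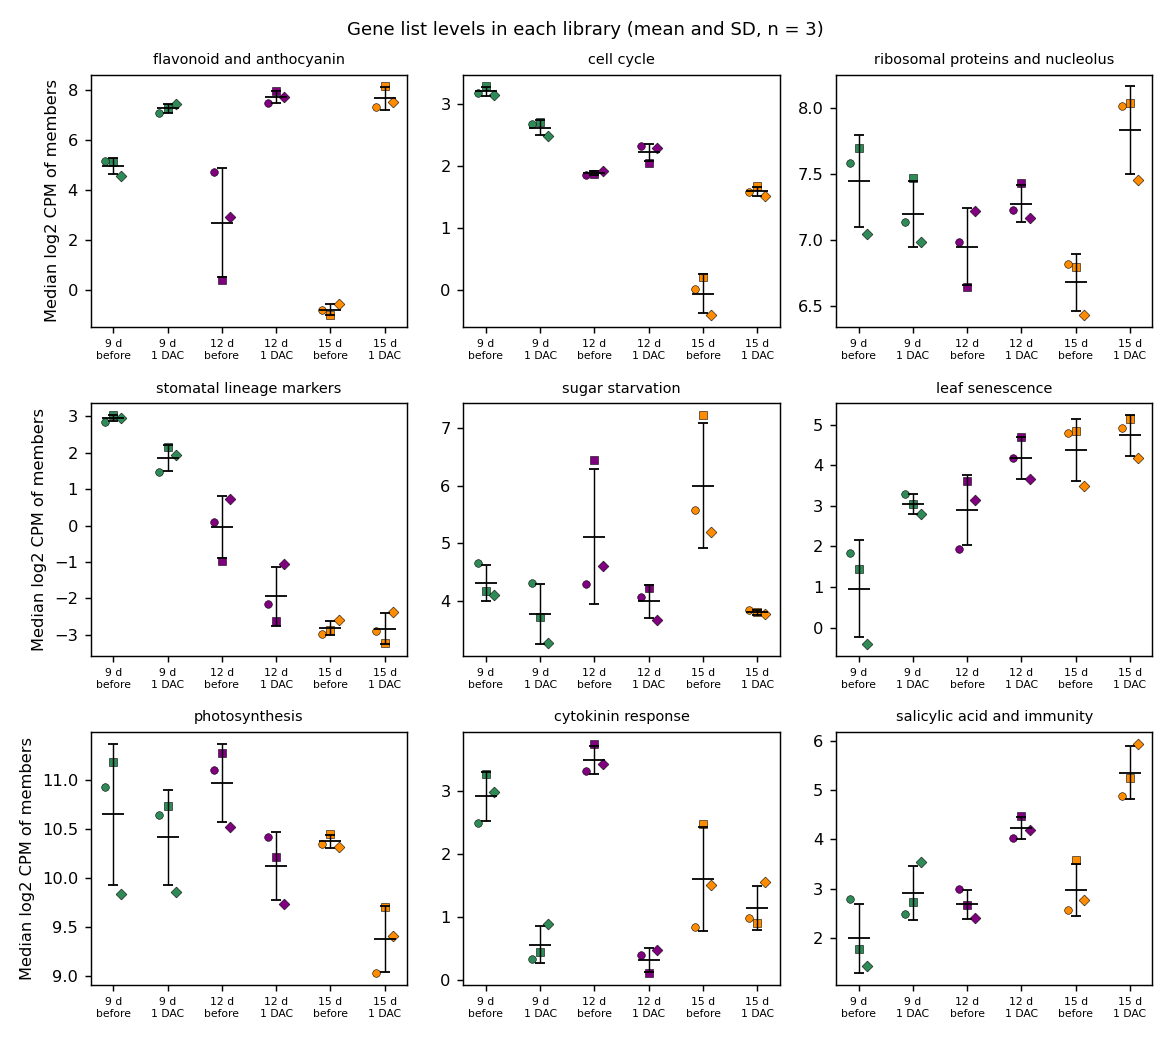
Each panel shows the median log2 CPM of the tested members of a gene list in each library (circle for replicate 1, square for 2, diamond for 3, bars for mean and SD, n = 3), by age before culture and 1 day after culture (1 DAC). The cell cycle panel falls with age before culture (median log2 fold change of -3.34 between 15 and 9 days), and the flavonoid and anthocyanin panel is higher after than before culture at each age.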

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

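Chosen only after the result was seen were the tests of a wrong age label, of cultured leaf under a time-0 label, of the 15-day replicate 2 library and of replicate 3 as a batch, of depth and a separate batch for replicate 3, and the splits of the 9 comparisons of 2 groups.

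The change over culture differed between ages by a test of the difference itself, which is what drew attention to the results that follow. Between 15 and 9 days 4360 genes differed, between 12 and 9 days 11 (2217 at an unadjusted p under 0.05, 433 by DESeq2) and between 15 and 12 days 582. Among gene lists, the median differences of log2 fold changes at 15 against 9 days were 2.78 for cell cycle genes, 1.93 for ribosomal proteins and nucleolus, 4.40 for flavonoid and anthocyanin genes and 1.23 for salicylic acid and immunity genes (1.32 with ALD1 at its bound). They were -2.21 for sugar starvation genes, -1.85 for auxin response genes, -1.23 for ethylene genes, -1.15 for circadian clock genes and -0.77 for photosynthesis genes. The camera call of the cell cycle list held with an estimated correlation (adjusted p = 0.00228), and those of the other 8 lists did not.

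Single genes differed likewise by edgeR's quasi-likelihood test. Upward stood the storage protein gene VSP2 at 6.20, the cyclin CYCB1;1 at 3.97, the growth gene ANT at 1.15, the pigment genes PAP1, DFR and 5MAT at 4.37, 8.60 and 8.79, the lipid transfer gene LTP4 at 10.53, the wax synthesis gene CER1 at 9.47 and the beta-amylase gene BAM5 at 8.97. AT3G02480, a late embryogenesis abundant family gene, had a fitted difference of 12.02, where at 15 days it went from 2 to 3184 counts, 1236-fold (95% counting interval 342 to 10213). Downward stood SPL3 and SPL10 at -1.89 and -1.99, the NAC gene ORE1 at -4.55, SEN1 at -7.71, the defensin genes PDF1.2c and PDF1.2b at -9.76 and -8.19, which are similar copies, and the anthocyanin acyltransferase gene AACT1 at -8.09. The peroxidase gene Prx37 had a fitted difference of -8.19, where at 9 days it went from 1 to 3276 counts, 3396-fold (95% counting interval 609 to 134175). VSP2, CYCB1;1, DFR, BAM5, 5MAT, AT3G02480 and PDF1.2c stayed called under each alternative followed for single genes. These were RLE factors, DESeq2, no filter on low counts, the replicate block, the batch term, leaving out the 2 libraries that stood apart and leaving out each replicate. ANT, Prx37, SEN1, ORE1, PAP1 and SPL3 lost the call when any 1 replicate was left out, LTP4 without replicate 1 or 3, CER1 without replicate 2, and SPL10, PDF1.2b and AACT1 without replicate 1. ANT also lost it with no filter on low counts, and ANT and Prx37 did without both libraries that stood apart.

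Other splits of the libraries were compared with the real one. For the average culture response, 1 of 80 splits, the real one, gave the real 9342 genes. The next gave 7382, a split that keeps the real labels at all but 1 age. Such splits mix cultured and uncultured leaves within an age, which widens the spread within groups. They stand for no culture effect at any age, and against that the real count stood out among the 80. They do not show how many of the 9342 genes would be called by chance. For the difference between 15 and 9 days, 1 of 25 splits, the real one, gave the real count. The highest other gave 2938, a split with the real ages at 1 of the 2 times. These splits reshuffle the 2 ages within each time, so each split keeps the culture effect. They stand for no age effect at either time, not for an equal culture response at both ages. Mixing ages that differ also widens the spread within groups, so these splits cannot exclude chance for that difference. Chance cannot be excluded for 12 against 9 days, where 5 of 25 splits gave at least 11 genes. The highest of these, 457, came with the real ages at 1 time. Nor can chance be excluded for 15 against 12 days, where 2 of 25 gave at least 582. The highest there, 807, came with the real ages at neither time. A split for 12 against 9 days with the real ages at neither time gave 96, several times the real count. A time with its 2 ages fully swapped also counts as neither, so such splits can still hold an age contrast. What gave these counts was not tested. For the 9 comparisons of 2 groups, 10 splits are too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave the real count or more, and the highest other gave 0 genes, except 15 against 12 days before culture, where a split that puts 12-day replicate 2 with 15-day replicates 1 and 2 gave 2601 against the real 3048. The 0 genes of the other splits are adjusted counts by edgeR. All 3 replicate numbers correlated above 0.1 for culture at 9 days, 12 against 9 days after culture and 15 against 12 days before culture. In these, the other splits that part the libraries of each number also gave 0 genes by edgeR.

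The difference in culture response between 15 and 9 days was weighed against technical explanations. It does not rest on the 15-day replicate 2 library before culture alone, since 4075 genes differed between 15 and 9 days without it. Leaving out replicate 3, 2278 genes still differed, so the difference is also seen in replicates 1 and 2. Counts were 762 without replicate 1 and 1870 without replicate 2. Each group holds 1 replicate 3 library, so a comparison of these counts does not test replicate 3 as a batch. A candidate explanation is that 15-day leaves leave a low-sugar state in culture. Of 10 low-sugar genes, 4 differed downward and 1 upward without both libraries that stood apart (median -2.04). At least 5 downward had been set as the mark. With all 18 libraries STR18 differed upward by 3.02. The low-sugar explanation stays open, as do a biological effect of age itself and detachment or loss of sucrose, which the design does not separate.

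Replicate 2 before culture at 12 and 15 days stood apart from its groups, with high early stress and touch genes in both. A wrong age label is argued against by the cell cycle median, which was 1.70 log2 units higher in the 12-day than in the 15-day library, each near its own age. Across all genes the age of the 12-day library is less clear. It correlated at 0.935 and 0.948 with replicates 1 and 3 of its group. With uncultured 15-day replicates 1, 2 and 3 the values were 0.942, 0.944 and 0.929. Cultured leaf under a time-0 label is argued against by flavonoid and anthocyanin genes, whose median lay at -0.85 or lower relative to the group's other libraries. A low-sugar or dark state may contribute, since a separate list of 10 low-sugar genes had median deviations of 1.86 and 1.92, at percentile 100 of 10000 random lists of matched expression in both libraries. The random lists hold unrelated genes, so an extreme percentile can also arise for any list whose genes move together. The percentile alone therefore does not single out a low-sugar or dark state. Whether handling or time of harvest brought it about was not tested.

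Replicate 3 libraries deviated together in all groups. Depth itself is argued against as the cause, since with each library thinned at random to the lowest total the lowest of the 15 correlations between replicate 3 libraries was 0.130. A separate batch, for which the labels give different tags, stays open, since the 15 correlations between replicate 3 libraries (lowest 0.136 across genes) are the pattern itself and decide nothing. No biological explanation was tested, since the design names none for replicate numbers.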

How the results depend on the processing

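Chosen after the data were seen were the batch term for replicate 3 and the fit without replicate 2 before culture at 12 and 15 days (the 2 libraries that stood apart). The counts below are genes past the threshold by edgeR's quasi-likelihood test unless a tool is named.

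Counts not listed stayed within 1.5 times the main count. With the replicate number as a block, counts were 3084 for culture at 9 days (1999 without it), 2629 for 12 against 9 days (1559) and 4665 for 15 against 12 days before culture (3048), 1626 for 12 against 9 days (942) and 271 for 15 against 12 days after culture (41), and 50 (11) and 1442 (582) for the same differences of culture responses. The block changed the call of 18 of 738 called values of named genes and of 3 of 87 called lists. With a batch term the counts were 2571 for 12 against 9 days before culture, 1555 and 301 for 12 against 9 and 15 against 12 days after culture, and 59 and 1273 for those differences. Without the 2 libraries that stood apart they were 3844 for culture at 9 days, 1625 shared by the ages, 2023 and 723 after culture, and 58 and 1506 for the differences. DESeq2 gave 3044 for culture at 9 days, 2748 for 12 against 9 days before culture, 1652 and 759 after culture, and 433 and 1473 for the differences. The cause of these moves was not tested.

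With only the compared groups in the fit, and so fewer libraries to estimate the spread, counts were 2634 and 5332 for culture at 12 and 15 days, 5561, 580 and 24 for 15 against 9, 12 against 9 and 15 against 12 days before culture, 0 for 15 against 12 days after culture (4026 at an unadjusted p under 0.05), and 39 and 9 for the last 2 differences. With a mean of at least 5 CPM, and so fewer genes tested, they were 805 before culture for 12 against 9 days, and 3235 and 514 after culture for 15 against 9 and 12 against 9 days.

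Leaving out 1 replicate or library, and so fewer samples, gave 316 to 1475 for culture at 9 days, 1668 to 3572 for culture at 12 days, 4495 to 8608 for culture at 15 days, 5539 to 9829 for the average culture response, 193 to 592 for calls shared by the 3 ages, 5920 to 9609 for age before culture, 15 against 9 days, 146 to 2161 for 12 against 9 days, 551 to 4350 for 15 against 12 days, 883 to 3892 for age after culture, 15 against 9 days, 50 to 746 for 12 against 9 days, 0 to 24 for 15 against 12 days, 762 to 4888 for difference of culture responses, 15 against 9 days, 0 to 53 for 12 against 9 days, 0 to 1226 for 15 against 12 days. The counts of 0 by edgeR come with 830, 1541 and 1906 genes at an unadjusted p under 0.05 without replicate 1, in the order above. The lowest count of each range was that without replicate 1, and a count of 0 was also reached in other settings.

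Of the 738 called values of named genes, the call and direction stayed for 735 with RLE factors, 715 with DESeq2 (2 lost), 717 with no filter on low counts, 734 with the batch term and 667 without the 2 libraries that stood apart. They stayed for 468, 547 and 510 without replicates 1, 2 and 3. The sign turned for ABR1 before culture (-1.17 without those 2 libraries, -1.15 to 8.13 without 1 replicate), for ACS8 before culture (-0.17 to 6.86 without 1 replicate), for AT1G06360 in culture at 15 days (0.10 without those 2 libraries, -5.21 to 0.20 without 1 replicate) and for TAT3 in culture at 9 days (-0.0072 to 5.11 without 1 replicate). Of 164 list calls at a preset correlation over all contrasts, 18 held with an estimated correlation. In 7 of the contrasts described, 87 lists were called, and 87 stayed so with RLE factors, 78 with fry, 77 without the 2 libraries, 83 with the batch term and 9 with an estimated correlation. The cell cycle calls for 12 against 9 and 15 against 12 days before culture, outside these 7, stayed under each of those settings.

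Depth limits genes at few counts, such as WOX12 and YUC4 with at most 5 and 8 counts in any library. In simulated counts, for genes with a mean of at least 5 CPM, 3% of 2-fold differences of culture responses between 15 and 9 days were called. For 2-fold changes in the average response it was 75%.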

Other observations

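The product classes below were chosen only after the results were seen, as the strongest of 123 classes with at least 15 tested genes, grouped by the reference's product names. Adjusted p-values are from limma's camera with Benjamini-Hochberg adjustment over the 123 classes of a comparison.

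In the average culture response, lipid-transfer and 2S albumin family genes rose (of 35 genes 19 higher and 8 lower, median 1.02, adjusted p = 1.91e-07, adjusted p = 0.435 with an estimated correlation), as did peroxidases (of 34 genes 19 higher and 5 lower, median 1.43, adjusted p = 5.67e-06, adjusted p = 0.435 with an estimated correlation) and FAD-binding berberine enzymes (of 19 genes 10 higher and 2 lower, median 1.47, adjusted p = 7.44e-05, adjusted p = 0.435 with an estimated correlation). SAUR-like auxin-responsive genes fell (of 60 genes 10 higher and 39 lower, median -1.42, adjusted p = 0.000102, adjusted p = 0.639 with an estimated correlation), as did NPH3 family genes, which act in blue-light responses (of 27 genes 17 lower, median -0.68, adjusted p = 0.000269, adjusted p = 0.639 with an estimated correlation). Before culture, microtubule motor genes were lower at 15 than at 9 days (of 15 genes 13 lower, median -1.87, adjusted p = 5.44e-07, adjusted p = 0.299 with an estimated correlation), as were pectin lyase-like genes (of 45 genes 3 higher and 23 lower, median -1.38, adjusted p = 3.72e-06, adjusted p = 0.299 with an estimated correlation) and histones (of 30 genes 2 higher and 19 lower, median -0.96, adjusted p = 1.07e-05, adjusted p = 0.715 with an estimated correlation), while TIR-NBS-LRR resistance genes were higher (of 45 genes 25 higher and 1 lower, median 0.97, adjusted p = 0.00173, adjusted p = 0.760 with an estimated correlation). After culture, microtubule motor genes were still lower at 15 days (of 15 genes 10 lower, median -1.13, adjusted p = 5.71e-06, adjusted p = 0.410 with an estimated correlation). In the difference of culture responses between 15 and 9 days, histones differed upward (of 30 genes 17 with an upward difference and 1 with a downward difference, median 1.25, adjusted p = 4.13e-08, adjusted p = 0.756 with an estimated correlation) and the SAUR-like class was called downward (of 60 genes 1 with an upward difference and 19 with a downward difference, median -1.92, adjusted p = 0.000106, adjusted p = 0.756 with an estimated correlation). The Homeodomain-like class was also called downward, the 1 class among these called with an estimated correlation (of 59 genes 1 with an upward difference and 7 with a downward difference, median -0.70, adjusted p = 0.00178, adjusted p = 0.0377 with an estimated correlation).

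Low-sugar genes, 10 of them listed apart from the sugar starvation list, were followed across comparisons. In culture at 15 days 8 fell and 1 rose (median -4.30), and before culture 7 were higher and 1 lower at 15 than at 9 days (median 2.95), or 4 higher and 1 lower without the 2 libraries that stood apart (median 1.54). Medians were -1.13 for culture at 9 days and -0.20 for 15 against 9 days after culture, where none of them was called by edgeR. AT4G27450 and DRM2, a dormancy-associated gene, differed most clearly downward between 15 and 9 days, by -5.89 and -3.87 on the log2 scale with all 18 libraries.

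Some values fall outside the comparisons. Plastid-encoded genes held 0.293% and 0.329% of counts in replicate 2 before culture at 12 and 15 days, and 0.305% in 9-day replicate 2 after culture, against a median of 0.0621% over the 18 libraries. Ribosomal RNA genes held 0.164%, 0.174% and 0.194% in the same libraries. The 10 genes with the most counts took 4.69% to 14.1% of a library. Among the fixed genes, GRF5 had at most 12 counts in any library.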
